A study of Mus musculus with 12 samples.

How the data were processed

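Total RNA of mouse embryonic stem cells was measured on 12 one-colour (Cy3) arrays of a mouse expression design with 62976 spots, 4 for each of WT, Id1KO and Id1KO_Zrf1KD. Per the labels, the cells grew in serum with leukaemia inhibitory factor, the knockdown used a lentiviral hairpin with puromycin selection in the knockout cells, and the 4 samples of a group were independent biological samples. Per the file headers, the scanner files were made with Agilent Feature Extraction 10.7.3.1 and hold each spot's intensity: a raw mean signal, a local background median, and a processed signal that was background subtracted and detrended within the array and not normalized between arrays. They also hold flags of 0 or 1 per spot. Probe coordinates are those of the files, build mm9. The deposited table holds log2 values, and every column has a median of 6.55. Quantile normalization between arrays would give equal medians, but these alone do not show which method was used. Its identifiers are spot numbers, found by matching each column to the scanner file of its sample. Its background correction is not stated, and from the values it is close to a normexp correction of the raw mean signal.

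For each array, log2 of the processed signal minus that array's 75th percentile over all non-control spots was computed, and then averaged over the spots of a probe without spots that the software marked as non-uniform or as population outliers (108 to 302 of the spots per array). No spot was saturated. Of 55681 non-control probes, 30879 were well above background, on at least 50% of their spots, on all 4 arrays of at least 1 group and were kept, and the brightest probe stood for each gene name, which gave 22590 features, here called genes. Of these, 8905 carry a locus, clone or transcript name or a symbol of a set-aside kind, and 215 lack a value on an array. The set-aside kinds are Gm-number and Rik genes and olfactory and vomeronasal receptor genes. All 8905 are here called features without a gene symbol, although the class includes annotated genes. Signal over background limits dim genes: where a group had no array well above background, the fold change is given as a lower bound ("at least"), against that group with each value raised, where lower, to the lowest level of any probe well above background on the same array. The bound holds for the processed signal, and folds are smaller with normexp or the deposited values.

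The groups were compared with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8, for reading), in 1 fit with a mean per group, by limma's moderated test, two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Genes with an absolute log2 fold change of at least 1 were also counted. The 28 gene lists, fixed before the data were examined, were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The shift of a list is its median log2 fold change minus that of all genes tested. Chromosomes were compared by a two-sided permutation of genes, with 1e+05 medians of random gene sets drawn from their exact distribution, adjusted over the chromosomes and given as a description, since genes are not independent replicates. Before adjustment the smallest p that these can give is 1e-05. The lists were naive pluripotency, general pluripotency, formative and primed epiblast, neural, primitive streak and mesoderm, endoderm, trophoblast, germline, 2-cell-like, Id and basic helix-loop-helix partners, BMP-SMAD, Wnt, Notch and FGF-ERK targets, retinoic acid response, Hox, Polycomb, chaperones, stress and unfolded protein response, cytosolic ribosomal proteins, p53 targets and apoptosis, cell cycle, interferon response, extracellular matrix and adhesion, fibroblast markers, imprinted, Y-linked and X-inactivation centre genes.

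The genes named follow a rule fixed before the data were examined. Among genes with an adjusted p under 0.05, an absolute log2 fold change of at least 1, no overlap of the 4 against 4 values and a gene symbol, it took the 8 highest and 8 lowest of the genes above background on at least 1 array of both groups and the 4 largest lower bounds each way. It added up to 4 members of each list with the smallest adjusted p per comparison, 5 genes of each pattern over both steps, and always Id1, Dnajc2, Nanog, Pou5f1, Sox2, T, Pax6, Sox1, Cdx2 and Gata6.

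The arrays came from 3 slides. The fit was repeated with the slide as a block, and fold changes were also taken within each slide. The replicate numbers were checked as a pairing: across the groups, deviations from the group mean had a median correlation across genes of -0.20 for arrays of the same number and 0.24 for arrays of the same slide, and 1 of 12 arrays was closest to the array of its own number in another group. The numbers were therefore not used as pairs, and with the replicate number as a block 15778, 15788 and 14066 genes passed in the 3 comparisons, in the order of the report. Other alternatives were a normexp background correction with an offset of 50, quantile normalization, the 75th percentile over probes above background on all arrays, the deposited values, no filter on dim probes, the mean over a gene's probes, only the arrays of the 2 groups compared, a trended and robust variance model, each array left out in turn, and fry as the list test. Centring on the median of tested genes, features with a gene symbol only, and autosomal features only were added after the data were seen.

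The fit and the list test were tried on simulated data with 22590 genes that varied independently, without slide effects or the scaling step. In Id1KO against WT, 52.2%, 76.1% and 93.9% of genes changed by 0.5, 1 and 2 log2 units were recovered, with 7 unchanged genes among 155 called. In Id1KO_Zrf1KD against Id1KO the shares were 67.9%, 84.3% and 97.0% (20 of 352), and in Id1KO_Zrf1KD against WT 77.6%, 89.6% and 98.5% (10 of 187). The raised gene list was found by camera, and 0 of 20 unchanged lists had an unadjusted p under 0.05. This does not cover lists whose genes are correlated, nor the scaling of arrays that differ in many genes.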

Results

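Gene expression was measured on 12 one-colour arrays in mouse embryonic stem cells of 3 groups with 4 arrays each: wild type (WT), an Id1 knockout line (Id1KO), and the Id1 knockout line after knockdown of Zrf1 (Id1KO_Zrf1KD). Id1 is a helix-loop-helix protein that binds and inhibits basic helix-loop-helix transcription factors, and Zrf1 is a J-domain protein encoded by the gene that the array lists as Dnajc2. Per the labels, the 4 samples of a group were independent biological samples. The sample titles name no separate lines within a group. The spread within a group is therefore read here as that of cultures of 1 line per genotype and not of separate lines. Across the arrays, 54.8% to 59.3% of spots were well above background, and the 75th percentile of the processed signal lay between 393.3 and 596.5 units. It went with the group: 440.7 to 550.2 in WT, 393.3 to 491.8 in Id1KO and 554.0 to 596.5 in Id1KO_Zrf1KD. The ranges of Id1KO and Id1KO_Zrf1KD did not overlap. This difference in array brightness was not separated from the differences between the groups. Levels correlated across genes with r between 0.987 and 0.996 within a group and between 0.950 and 0.960 between groups. The arrays came from 3 slides, each of which held all 3 groups. The number of arrays, 4 per group, limits the precision of every value.

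The targeted genes were examined first. Dnajc2 (Zrf1) was strongly lower after the knockdown. Its level, in log2 units above the array's 75th percentile, was 2.0 ± 0.12 (SD, n = 4) in WT, 1.89 ± 0.11 in Id1KO and -0.27 ± 0.08 in Id1KO_Zrf1KD, which is 4.47-fold lower than in Id1KO (limma adjusted p = 9.7e-10) and 4.80-fold lower than in WT (adjusted p = 4.9e-10). Within the slides the log2 fold change against Id1KO was -2.28, -2.08 and -2.05. Its 1 probe lies on chromosome 5 at 21272454 to 21272513 (mm9). Id1 was not lower in the samples labelled Id1KO: the level was 0.86 ± 0.20 in WT, 1.23 ± 0.31 in Id1KO and 0.68 ± 0.16 in Id1KO_Zrf1KD. The log2 fold change of Id1KO against WT was 0.37 ± 0.15 (SE, adjusted p = 0.052), and it was 0.12, 0.49 and 0.43 within the slides. With the slide as a block the adjusted p was 0.0016. The 1 Id1 probe lies on chromosome 2 at 152563083 to 152563142 (mm9) and starts at base 847 of its target transcript. The extent of the deletion is not given in the sources used here, so this probe neither checks the knockout nor argues against it.

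**Figure D1:**
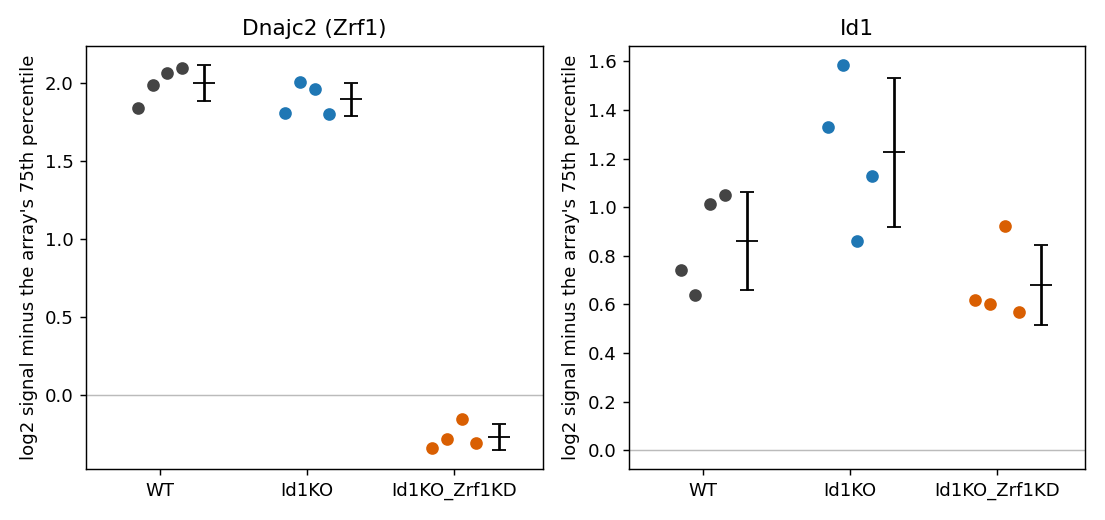
Level of Dnajc2 (Zrf1, left) and Id1 (right) on each array, as log2 signal minus the array's 75th percentile, by group. Points are arrays and bars show the mean ± SD of 4 arrays; Dnajc2 averaged -0.27 in Id1KO_Zrf1KD against 1.89 in Id1KO, and the Id1 probe averaged 1.23 in Id1KO against 0.86 in WT.

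The comparison of Id1KO with WT asks which genes differ between the cells labelled as lacking Id1 and wild-type cells. In Id1KO, genes of the formative and primed epiblast and of the 2-cell-like state lay higher, and genes of naive pluripotency and of the trophoblast lay lower. Fgf5, a growth factor of the early epiblast, was not well above background on any WT array and was at least 15.3-fold higher in Id1KO (down to 4.29; adjusted p = 2.6e-12). Here and below, "down to" gives the smallest fold under the other scalings, normexp and the deposited values, where the fold or bound printed is over 1.5 times as large. Lef1, a transcription factor of Wnt signalling, was 28.8-fold higher (adjusted p = 3.3e-14), Lefty1, a secreted Nodal antagonist, 8.29-fold, and Otx2, a transcription factor of the epiblast and forebrain, 6.71-fold. Of the 19 tested genes of the formative and primed list, 15 rose and 3 fell. The median of the list lay 0.90 log2 units above that of all genes (camera adjusted p = 0.0017) and between 0.91 and 0.98 within the slides. Of 16 genes of the 2-cell-like list, 15 rose and 1 fell, with a shift of 2.72 (adjusted p = 3.8e-06; 2.62 to 2.78 within the slides). They included Zscan4a (28.2-fold), Zscan4c (28.5-fold) and Zscan4f (20.9-fold), members of a gene family transcribed in the 2-cell embryo; its copies are near identical, so their probes may share signal. The size of that shift was 1.24 with the normexp background correction and 1.31 with the authors' deposited values.

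Of 20 naive pluripotency genes, 15 fell and 4 rose, with a shift of -0.92 (adjusted p = 5.3e-05) that was -0.94 to -0.92 within the slides. Tbx3 was 3.46-fold lower, Prdm14 2.97-fold, Nr5a2 2.03-fold, Nanog 2.02-fold and Fgf4 1.75-fold. The general pluripotency list moved the other way: 14 of its 18 genes rose and 1 fell (shift 0.30, adjusted p = 0.0049; 0.25 to 0.33 within the slides; 0.15 without a filter on dim probes and 0.49 among features with a symbol alone), among them Dppa2 (3.16-fold), Lin28b (2.92-fold) and Dppa4 (1.78-fold). Pou5f1 (Oct4), the central pluripotency factor, had a log2 fold change of -0.11 ± 0.17 (SE, adjusted p = 0.57), and this was -0.40 with quantile normalization (adjusted p = 0.026) and -0.38 with the deposited values (adjusted p = 0.019). Without Id1KO replicate 3 the sign for Pou5f1 turned, since Id1KO_Zrf1KD then had log2 fold changes of -0.37 against Id1KO and -0.29 against WT. Sox2 was 1.16-fold lower (adjusted p = 0.0046).

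Of 19 trophoblast genes, 14 fell and 1 rose (shift -0.90, adjusted p = 8.1e-05; -0.98 to -0.89 within the slides), led by Esx1 (6.29-fold lower), Ets2 (2.87-fold), Ascl2 (1.97-fold) and Tcfap2c (1.91-fold). In the primitive streak and mesoderm list 11 of 18 genes fell and 3 rose (shift -0.73, adjusted p = 0.040; -0.84 to -0.73 within the slides). Cdx1 was 5.41-fold lower and Gsc, not well above background in Id1KO, at least 8.97-fold lower (down to 2.80), while Wnt8a, not well above background in WT, was at least 12.8-fold higher (down to 3.12). Kdr had a log2 fold change of 1.27 on its brightest probe and of -2.64 on its other probe. The mesoderm shift was -0.34 with the deposited values, and its call did not hold with an estimated correlation (adjusted p = 0.10), with normexp (adjusted p = 0.11) or with quantile normalization (adjusted p = 0.055). Of 32 Hox genes 17 fell and 8 rose (shift -0.82, adjusted p = 0.031; adjusted p = 0.20 with an estimated correlation and 0.093 with normexp; -0.28 with the deposited values and -0.50 without Id1KO replicate 1; -0.82 to -0.70 within the slides), with Hoxc4 8.75-fold (down to 3.72) and Hoxc13 4.30-fold (down to 2.66) lower and Hoxb1 at least 2.39-fold higher (down to 1.44). Extracellular matrix and adhesion genes fell in 18 of 24 cases and rose in 4 (shift -0.51, adjusted p = 0.0026; -0.51 to -0.48 within the slides; -0.32 among features with a symbol alone), as for Col4a2, a basement membrane collagen chain (2.44-fold lower). Fibroblast markers, listed as a sign of other cells in the cultures, fell in 13 and rose in 5 of 22 cases (shift -0.68, adjusted p = 0.011; adjusted p = 0.10 with an estimated correlation; -0.80 to -0.51 within the slides), with Col5a1 3.02-fold and Pdgfrb 2.95-fold lower and S100a4 6.33-fold higher. Among features with a gene symbol alone, a setting chosen after the data were seen, the mesoderm, Hox and fibroblast calls did not pass (adjusted p = 0.26, 0.26 and 0.11).

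Of 41 cytosolic ribosomal protein genes 39 rose and none fell (shift 0.46, adjusted p = 2.0e-07; 0.42 to 0.47 within the slides), with Rps7 1.98-fold and Rps19 and Rps25 both 1.95-fold higher. The call did not hold with quantile normalization (shift 0.06, adjusted p = 0.68), with the deposited values (0.08, adjusted p = 0.43) or with an estimated correlation (adjusted p = 0.26). The interferon response list did not pass as a list (shift 0.46, adjusted p = 0.25). Its median log2 fold change was 0.61, and 0.17 at the lowest of the scalings. Of its 21 genes 12 rose and 5 fell: Rtp4 was 21.3-fold (down to 4.56), Isg15 6.79-fold and Oasl2 at least 14.7-fold (down to 4.07) higher, and Xaf1 7.69-fold lower. Outside that list, Gbp2 (31.1-fold, down to 7.33) and Psmb8 (at least 30.0-fold, down to 7.32), genes known to respond to interferon, were among the largest increases, with Enpp2 (79.1-fold, down to 19), the enzyme autotaxin. Id3, a paralogue of Id1, was 5.62-fold higher, Myc 6.18-fold (down to 4.11) and Mycn 2.38-fold. In their list, Id and basic helix-loop-helix partners, 6 of 15 genes rose and 5 fell (shift -0.21, mean log2 fold change 0.32, adjusted p = 0.93). The imprinted gene list did not pass either (adjusted p = 0.54), with 13 of 23 genes higher and 8 lower, and the noncoding RNAs Meg3 and Mirg, transcribed from 1 imprinted cluster, were 5.33-fold and 5.15-fold higher.

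Sex-linked genes also separated WT from the other samples. Of 6 Y-linked genes 5 rose and 1 fell in Id1KO (shift 4.19, adjusted p = 0.033; adjusted p = 0.10 with an estimated correlation and 0.059 with the slide as a block; 3.95 to 4.41 within the slides; 1.17 with normexp and 1.0 with the deposited values). As 4 of the 6 were not well above background in WT, the shift rests on dim values: the median log2 fold change of the list was 4.34, and 2.6 with these genes at their lower bounds. Eif2s3y was at least 385-fold (down to 76.6) and Ddx3y at least 59.3-fold (down to 12.7) higher. Neither was well above background on any WT array. The median log2 fold change of 936 X-linked genes lay 0.27 units below the autosomal median (difference -0.27, permutation test over genes, adjusted p = 7e-05; -0.25, -0.24 and -0.25 within the slides). Autosomes passed this test too, by less: the difference was 0.19 for chromosome 12 and 0.15 for chromosome 13 (both adjusted p = 7e-05), and -0.10 to 0.09 for chromosomes 3, 7, 8, 9 and 11. Genes of X-linked families with testis and germline expression were among those with the lowest fold changes of the comparison: Xlr5b was 26.1-fold, Xlr5a 24.9-fold and Mageb4 15.8-fold (down to 8.5) lower. Along the X chromosome the difference lay in its proximal part: in 10 bins of about equal gene number, bins 1 to 6, which end at 98716190 (mm9), differed from autosomal genes by -0.99 to -0.45 in Id1KO, and bins 7 to 10 lay 0.13 to 0.24 higher. The 2 cell lines therefore differed in Y-linked and proximal X-linked expression. Ddx3y, Eif2s3y, Uty and Zfy1 were well above background on no WT array. Ddx3y and Eif2s3y were so on every array of the Id1KO line. For these genes this argues for different Y content of the lines and against an effect of the knockout on expression alone. For the X-linked genes, line content was not separated from an effect of the knockout. Every difference between Id1KO and WT named here is also a difference between these lines.

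**Figure D2:**
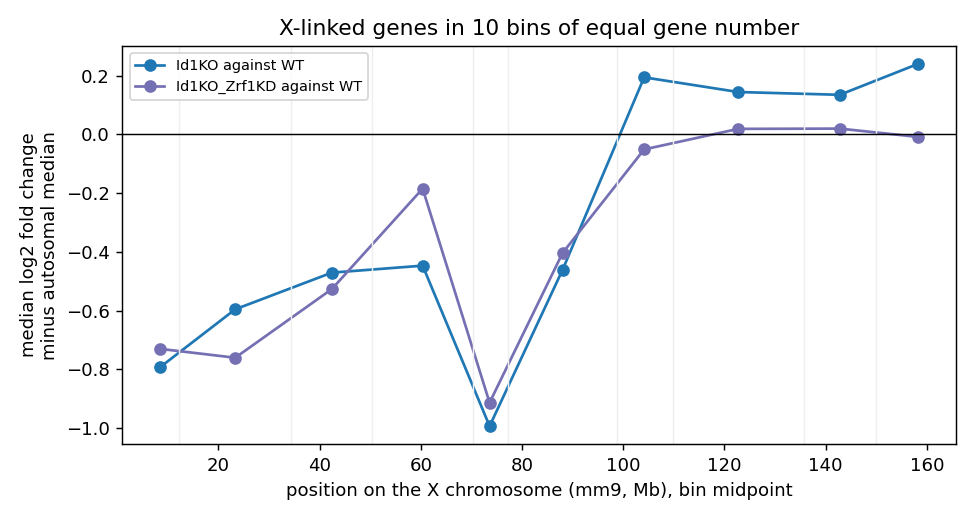
Median log2 fold change of X-linked genes minus that of autosomal genes in 10 bins along the X chromosome (mm9), for Id1KO against WT and Id1KO_Zrf1KD against WT. Bin 5 lay at -0.99 and -0.91, and bin 10 at 0.24 and -0.01.

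Over all genes, 9594 were higher and 6682 lower in Id1KO at an adjusted p under 0.05 among 22590 tested, of which 2752 and 1685 by at least 2-fold. The median log2 fold change of all genes was 0.15, and it was 0.02 with quantile normalization and 0.01 with the deposited values, so list shifts are given relative to all genes. Features without a gene symbol, a class that includes Gm-number, Rik and receptor genes, made up 8905 of those tested. They made up 1593 of the 2752 features higher by at least 2-fold. Their median log2 fold change was 0.44, against -0.04 for the 13685 features with a symbol. Of the features with a symbol, 4854 were higher and 5406 lower. With quantile normalization 7960 genes were higher and 7836 lower (2076 and 2169 by at least 2-fold), and with the deposited values 7897 and 7749 (1064 and 1154), so the balance of higher and lower genes depends on the setting. The remaining 17 of the 28 lists did not pass (adjusted p from 0.055 to 0.93): besides those given, these were the neural, endoderm, germline, Wnt, Notch, FGF-ERK, retinoic acid, BMP-SMAD, Polycomb, chaperone, stress response, p53, cell cycle and X-inactivation centre lists. The BMP-SMAD list, at adjusted p = 0.055, passed with the slide (adjusted p = 0.040) or the replicate (adjusted p = 0.0498) as a block. Adjusted over the list alone, the counts of higher and lower genes differed from those over all genes in 5 of the 28 lists, by 1 gene.

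**Figure D3:**
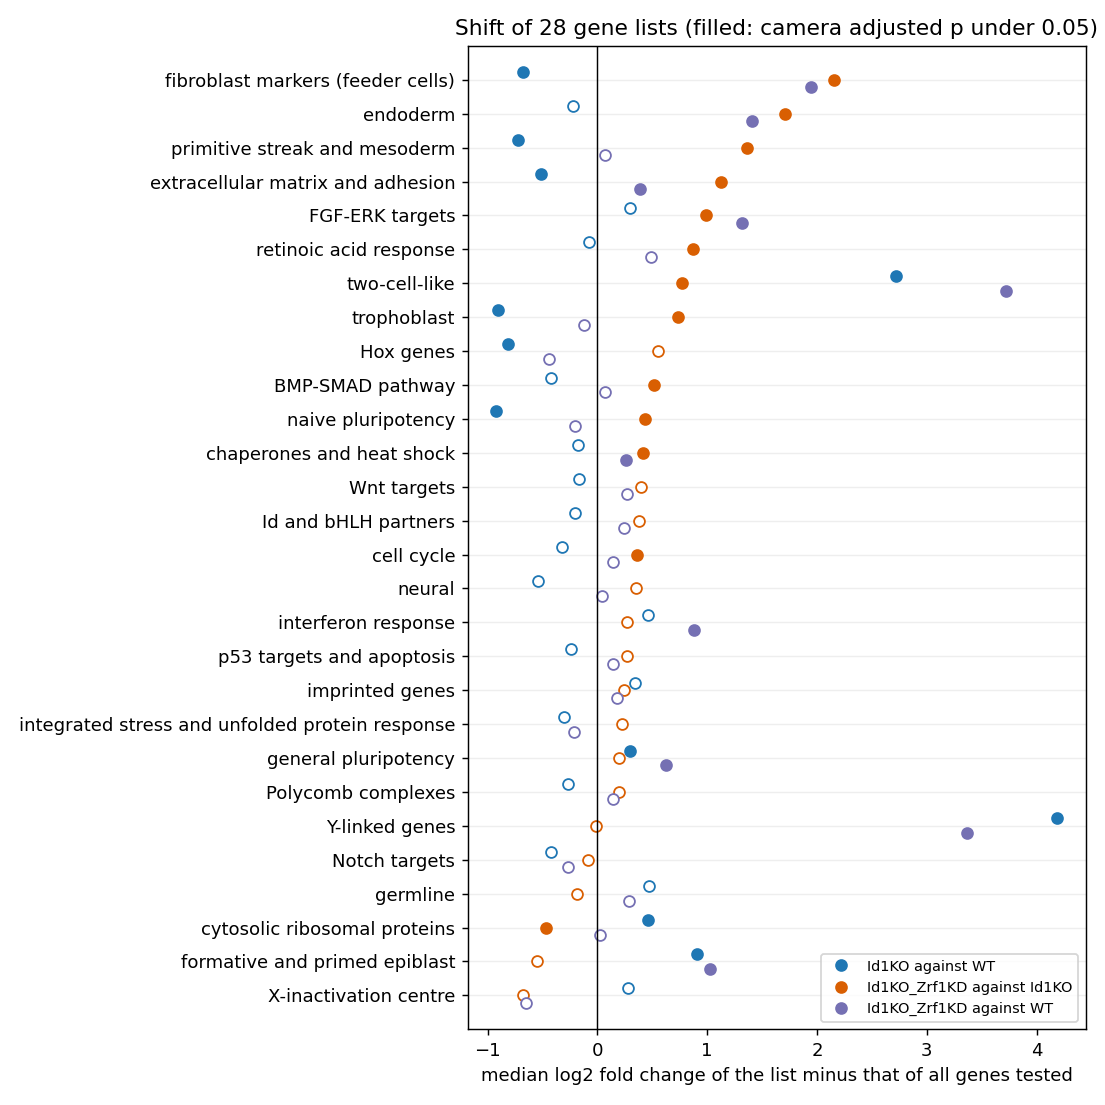
Median log2 fold change of each of 28 gene lists minus that of all genes tested, for the 3 comparisons. Filled points passed camera with the preset correlation at an adjusted p under 0.05; the fibroblast marker list lay at -0.68 in Id1KO against WT and at 2.15 in Id1KO_Zrf1KD against Id1KO, and the naive pluripotency list at -0.92 and 0.44.

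The comparison of Id1KO_Zrf1KD with Id1KO asks what the loss of Zrf1 changes in cells of the same knockout line. No knockout sample with a control hairpin was analysed here, so the comparison also holds the viral transduction and the puromycin selection. After the knockdown, the lists of FGF-ERK targets, endoderm, extracellular matrix and fibroblast markers lay higher. Egr1, a transcription factor induced by growth factor signalling, was 35.6-fold higher (log2 fold change 5.15 ± 0.06, SE; adjusted p = 3.1e-12), and Egr2, not well above background in Id1KO, at least 38.4-fold (down to 9.49). Fosb was 43.0-fold (down to 9.24), Fosl1 8.42-fold (down to 2.83), Fos 8.01-fold (down to 3.46), and Nab2, a corepressor of Egr proteins, 19.3-fold higher. In the FGF-ERK target list 13 of 17 genes rose and 3 fell (shift 0.99, adjusted p = 4.4e-04; 0.97 to 1.02 within the slides), with Phlda1 7.51-fold higher. With the scaling of the main fit, the largest increase of a gene measured in both groups was in Ereg, the growth factor epiregulin (58.9-fold, down to 18.1). Where Ereg was at its lowest Egr1 lay above it, since the smallest fold of Egr1 under any scaling was 29.9. The secreted proteases Mmp10 (27.1-fold, down to 8.10) and Mmp13 (19.6-fold), the interleukin 33 receptor Il1rl1 (23.1-fold, down to 6.09) and the pentraxin Ptx3 (19.3-fold, down to 7.26) were also among the 8 largest in the main fit.

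Of 20 endoderm genes 19 rose and none fell (shift 1.70, adjusted p = 4.9e-09; 1.70 to 1.72 within the slides). Col4a2 was 5.67-fold, Lama1 5.01-fold, Sparc 2.89-fold and Lamb1 2.88-fold higher, all products of the basement membrane that parietal endoderm secretes, and the endoderm transcription factor Gata6 was 3.50-fold higher. All 22 fibroblast markers rose (shift 2.15, adjusted p = 1.5e-11; 2.16 to 2.20 within the slides), among them Lox (11.6-fold, down to 6.17), Col1a2 (7.26-fold), Fbln2 (7.02-fold) and Acta2 (3.99-fold). Of 24 matrix and adhesion genes 18 rose and 2 fell (shift 1.13, adjusted p = 4.9e-06; 1.06 to 1.17 within the slides), with Col4a1 5.13-fold and Cdh2 3.72-fold higher. In the mesoderm list 12 of 18 genes rose and 3 fell (shift 1.36, adjusted p = 0.0068; 1.25 to 1.29 within the slides; 0.36 with normexp and 0.50 with the deposited values). This call did not pass among features with a symbol alone (shift 1.16, adjusted p = 0.11). Among its genes, Cdx1 was 5.47-fold, Bmp4 4.04-fold, Pdgfra 2.75-fold (down to 1.76) and Snai1 2.27-fold higher. T (brachyury) and Cdx2 were not well above background in Id1KO and were at least 2.24-fold (down to 1.15) and at least 4.51-fold (down to 1.73) higher.

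**Figure D4:**
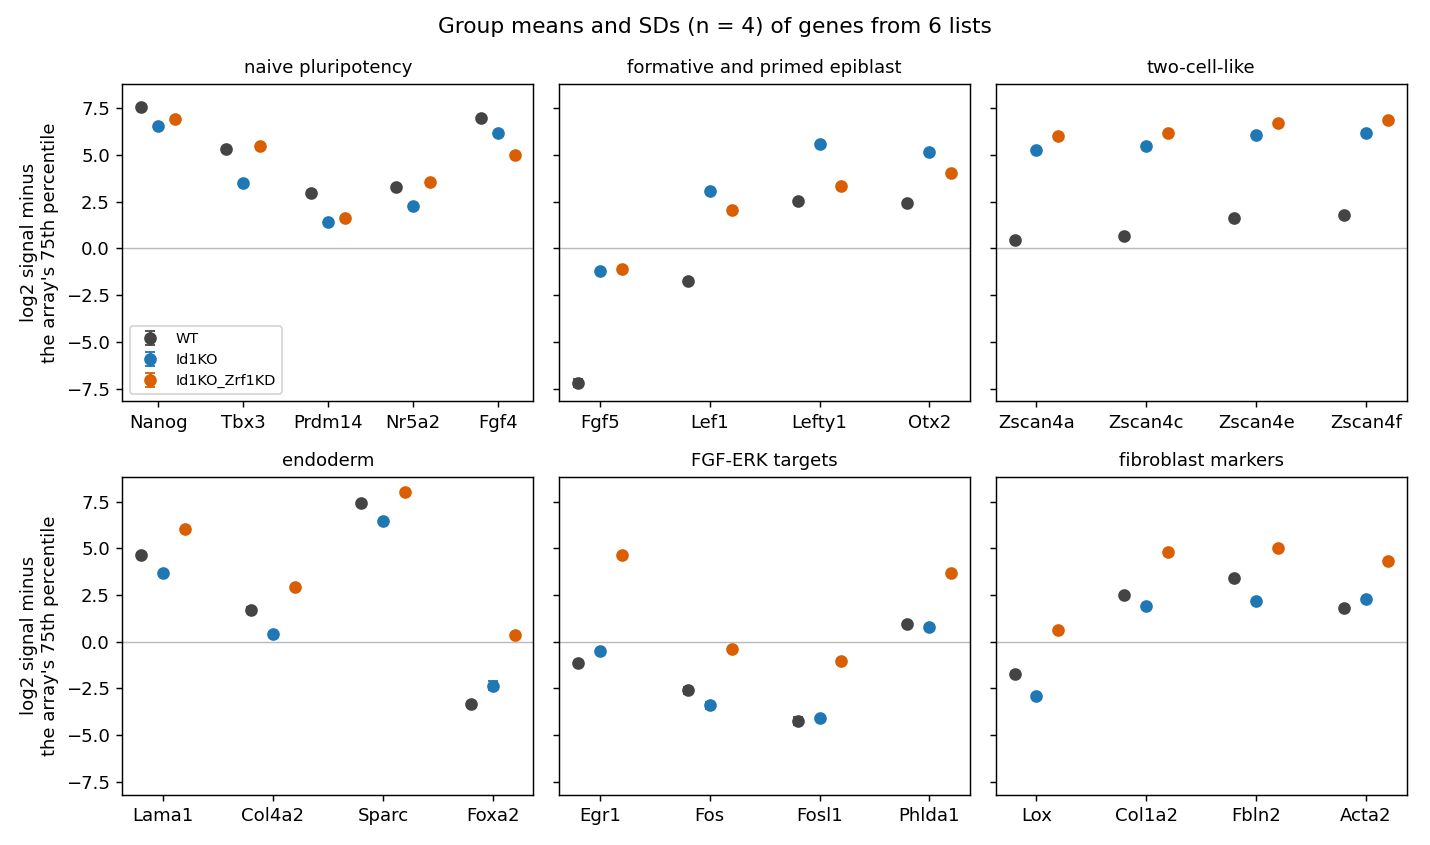
Mean level ± SD (n = 4) of 25 genes from 6 lists in the 3 groups, as log2 signal minus the array's 75th percentile; most SD bars are smaller than the points. Egr1 averaged 4.67 in Id1KO_Zrf1KD against -0.49 in Id1KO, and Zscan4c averaged 0.67 in WT against 5.50 in Id1KO.

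Trophoblast genes rose in 13 and fell in 2 of 19 cases (shift 0.73, adjusted p = 6.9e-04; 0.73 to 0.94 within the slides), with Tead4 5.05-fold (down to 3.13), Esx1 3.38-fold, Krt8 3.32-fold and Krt18 1.94-fold higher. In the BMP-SMAD list 11 of 17 genes rose and none fell (shift 0.52, adjusted p = 6.9e-04; 0.63 to 0.77 within the slides; 0.31 among features with a symbol alone), with Grem1, a secreted BMP antagonist, 6.89-fold, Id3 3.50-fold and Msx2 2.08-fold higher. Naive pluripotency genes rose in 14 and fell in 2 of 20 cases (shift 0.44, adjusted p = 0.0012; adjusted p = 0.054 with an estimated correlation; 0.45 to 0.49 within the slides; 0.23 among features with a symbol alone and 0.68 without a filter on dim probes). Spp1 was 4.85-fold, Tbx3 3.82-fold and Nr5a2 2.44-fold higher, whereas Fgf4 was 2.25-fold lower. Nanog had a log2 fold change of 0.37 on its brightest probe (adjusted p = 6.0e-05) and of -0.16 on its other probe, with opposite calls. The formative and primed list did not pass (shift -0.55, adjusted p = 0.098), and in it Lefty1 was 4.73-fold, Lefty2 2.63-fold and Lef1 2.03-fold lower. The 2-cell-like list rose further, with 13 of 16 genes higher and 1 lower (shift 0.77, adjusted p = 2.6e-04; 0.74 to 0.78 within the slides), as for Zscan4a (1.67-fold) and Zscan4c (1.62-fold).

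The retinoic acid response list had 11 of 15 genes higher and 2 lower (shift 0.87, adjusted p = 0.0072; 0.76 to 0.80 within the slides), with Cyp26b1, which degrades retinoic acid, 2.66-fold and Tgm2 2.57-fold higher. Of 28 cell cycle genes 20 rose and 3 fell (shift 0.36, adjusted p = 0.0013; 0.33 to 0.41 within the slides; 0.61 without a filter on dim probes): the cyclins Ccnd3 (2.66-fold) and Ccnd2 (2.62-fold) were higher, and the inhibitor Cdkn1b (2.69-fold) and Bub1 (1.61-fold) lower. Of 24 chaperones 16 rose and 6 fell (shift 0.42, adjusted p = 0.0086; adjusted p = 0.19 with an estimated correlation; 0.44 to 0.48 within the slides; 0.67 without a filter on dim probes), led by the small heat shock protein Cryab (5.65-fold higher). Among features with a symbol alone, the retinoic acid, cell cycle and chaperone calls did not pass (adjusted p = 0.11, 0.059 and 0.16). Ribosomal protein genes fell in 39 of 41 cases and rose in none (shift -0.47, adjusted p = 5.6e-09; adjusted p = 0.16 with an estimated correlation; -0.47 to -0.44 within the slides), and this shift was -0.22 without a filter on dim probes, -0.03 with quantile normalization (adjusted p = 0.50) and -0.03 with the deposited values (adjusted p = 0.30).

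The lowest fold changes of genes measured in both groups included NEAT2, the array's name for a nuclear noncoding RNA (12.8-fold lower), Ovgp1 (9.13-fold, down to 6.05), Meg3 (8.49-fold) and, in the imprinted list, Mirg (5.77-fold). In the stress response list, which did not pass (adjusted p = 0.32), Chac1 and Ddit3 (CHOP), which act downstream of the kinase PERK, were 6.22-fold and 6.07-fold lower, and Atf3 was 3.08-fold and Slc7a11 at least 2.78-fold (down to 1.57) higher. Of the neural list (adjusted p = 0.12), Sox21 was 5.84-fold (down to 2.95) higher, whereas Pax6 was 2.64-fold (down to 1.47) and Sox1 2.27-fold (down to 1.45) lower. Over all genes, 7294 were higher and 8988 lower, of which 1618 and 2978 by at least 2-fold, and 2194 of the latter were features without a symbol. Features without a symbol had a median log2 fold change of -0.50 and those with one of 0.11. The median of all genes was -0.09, and -0.19 when the 75th percentile was taken over probes above background on all arrays. The balance over all passing genes turned in other settings: 8035 genes were higher and 7676 lower with quantile normalization (1995 and 2201 by at least 2-fold, median 0.01), and 7990 and 7588 with the deposited values (912 and 1146, median 0.00). X-linked genes differed from autosomal ones by -0.04 (-0.05, -0.05 and -0.03 within the slides). The permutation gave them an adjusted p of 0.34 (unadjusted p = 0.16), and chromosomes 5, 12, 13 and 19 passed (0.08, -0.12, -0.12 and 0.10). Among features with a symbol alone the X-linked difference was -0.10 (unadjusted p = 0.0033 by the exact distribution of such medians). The other 15 lists did not pass (adjusted p from 0.053 to 0.89), although with the slide as a block the p53 list (adjusted p = 0.034) and the Id and basic helix-loop-helix partners (adjusted p = 0.042) passed. Counts adjusted over the list alone differed by 1 gene in 1 of the 28 lists.

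Id1KO_Zrf1KD against WT gives the sum of both steps. Here 7320 genes were higher and 7283 lower, of which 2041 and 2004 by at least 2-fold, and the median of all genes was -0.02. With the percentile over probes above background on all arrays the median was -0.13, with 5937 genes higher and 8844 lower (1794 and 2424 by at least 2-fold). Quantile normalization gave 6677 and 7693 (2027 and 1885), and the deposited values 6557 and 7640 (1018 and 819), so the even balance depends on the setting. Of 16 genes of the 2-cell-like list 14 rose and none fell (shift 3.72, adjusted p = 3.2e-09; 3.70 to 3.80 within the slides; 2.39 with normexp and 2.46 with the deposited values), with Zscan4a 47.1-fold and Zscan4c 46.1-fold higher. The formative and primed list (15 of 19 genes higher and 3 lower, shift 1.03, adjusted p = 6.5e-04; 0.82 to 0.94 within the slides) and the general pluripotency list (13 of 18 higher and 4 lower, shift 0.63, adjusted p = 0.0028; 0.52 to 0.65 within the slides) stayed above WT, and Fgf5 was at least 16.6-fold (down to 4.81) higher. The FGF-ERK target list was higher in 16 of 17 genes and lower in none (shift 1.32, adjusted p = 8.1e-08; 1.33 to 1.36 within the slides), with Egr1 56.0-fold higher. Endoderm genes were higher in 16 of 20 cases and lower in 2 (shift 1.41, adjusted p = 3.8e-06; 1.43 to 1.44 within the slides): Cubn and Dab2, which act in the endocytosis of visceral endoderm, were 16.2-fold and 15.4-fold (down to 8.54) higher, and Foxa2 12.8-fold (down to 6.03). Fibroblast markers were higher in 19 of 22 cases and lower in 2 (shift 1.95, adjusted p = 1.7e-07; 1.85 to 2.01 within the slides), and matrix genes in 16 of 24 and lower in 5 (shift 0.39, adjusted p = 0.0084; 0.39 to 0.44 within the slides). Interferon response genes were higher in 15 of 21 cases and lower in 3 (shift 0.88, adjusted p = 0.0093; 0.87 to 1.02 within the slides; 0.41 with normexp and 0.38 with the deposited values), with Oasl2, Isg15 and Ddx58 among them. Irgm1, an interferon-inducible GTPase outside that list, was 45.7-fold (down to 12.5) higher. Chaperones were higher in 15 of 24 cases and lower in 1 (shift 0.26, adjusted p = 0.0057; adjusted p = 0.24 with an estimated correlation; 0.25 to 0.31 within the slides).

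Naive pluripotency genes in Id1KO_Zrf1KD did not differ from WT as a list (shift -0.20, adjusted p = 0.34; -0.20 to -0.18 within the slides), with 7 of 20 genes higher and 11 lower: Fgf4 was 3.93-fold and Prdm14 2.59-fold lower and Gbx2 3.33-fold higher. Nanog was 1.56-fold lower (adjusted p = 7.5e-07) and Sox2 1.37-fold (adjusted p = 2.1e-05). Pou5f1 had a log2 fold change of -0.29 (adjusted p = 0.16). It was -0.44 with quantile normalization (adjusted p = 0.018) and -0.45 with the deposited values (adjusted p = 0.0081). Ribosomal protein genes had a shift of 0.02 (adjusted p = 0.90; -0.03, 0.04 and 0.04 within the slides). Id3 was 19.7-fold and Myc 12.8-fold (down to 8.20) higher. Of the sex-linked genes, Eif2s3y was at least 317-fold (down to 65.5) and Ddx3y at least 62.3-fold (down to 13.6) higher, 5 of 6 Y-linked genes rose (shift 3.36, adjusted p = 0.0018; 3.06 to 3.50 within the slides; 0.76 with normexp and with the deposited values; median log2 fold change 3.35, and 2.03 with dim genes at their lower bounds), and X-linked genes lay -0.29 from the autosomal median (adjusted p = 7e-05; -0.29, -0.27 and -0.31 within the slides), while 8 autosomes passed with differences of -0.11 to 0.10. Bins 7 to 10 of the X lay at -0.05 to 0.02. Between the 2 groups of the Id1KO line, 1 gene of the Y-linked list rose and 3 fell (adjusted p = 0.77). The other 18 lists did not pass (adjusted p from 0.12 to 0.90). Counts adjusted over the list alone differed by 1 gene in 7 of the 28 lists.

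Of the genes that passed in both Id1KO against WT and Id1KO_Zrf1KD against Id1KO, most had opposite signs, here called moved back. Among 12881 such genes 10538 (81.8%) had opposite signs: 6324 rose in Id1KO and fell after the knockdown, and 4214 fell and then rose. Features without a symbol carry much of this: of 4888 that passed in both, 4241 (86.8%) had opposite signs, 3652 of them higher and then lower. Of 7993 features with a symbol it was 6297 (78.8%), of which 2672 rose and then fell and 3625 fell and then rose. Independent lists of these sizes would share 5975 genes with opposite signs and 5756 with equal signs, against 2343 observed. The 2 comparisons are not independent, since both hold the Id1KO level, with opposite sign. A difference of Id1KO from both other groups therefore gives opposite signs by itself. Examples that rose and then fell are Gabra3, a GABA receptor subunit (at least 9.61-fold higher, down to 2.69, then 6.21-fold lower, down to 2.05) and Fut1 (8.02-fold, down to 2.86, then at least 12.9-fold, down to 3.59). Examples that fell and then rose are the transcription factors Pitx1 (11.2-fold lower, down to 3.26, then 6.59-fold higher, down to 2.17), Gata3 (6.95-fold, down to 2.65, then 6.31-fold, down to 2.47) and Egr4 (at least 6.30-fold, down to 2.0, then at least 21.5-fold, down to 5.20). Of the 10538 genes, 4250 did not pass in Id1KO_Zrf1KD against WT. Genes that rose at both steps numbered 1484, among them the chemokine Cxcl5 (5.01-fold, then 5.41-fold), Mmp10, Il1rl1, Lilrb4 and Dkk2. Mmp10, Il1rl1 and Dkk2 were not well above background in WT. Their first rise was at least 2.26-fold (down to 1.28), 1.87-fold (down to 1.24) and 1.86-fold, and that of Lilrb4 6.27-fold (down to 1.72). At both steps 859 genes fell, among them Dyrk4 (2.92-fold, down to 1.45, then 3.01-fold, down to 1.17) and S1pr5. The latter did not pass at the second step with the deposited values (-0.16, adjusted p = 0.057).

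Both comparisons use the Id1KO arrays, with opposite sign, so chance errors alone give opposite signs. Simulated unchanged groups that shared these arrays had a covariance of fold changes of -0.017, and the observed covariance was -0.35, a difference of -0.33. The simulation held no true change, so its 0 genes past in both comparisons were fixed in advance. A covariance also grows with the size of the changes. The correlation across genes was -0.43, no stronger than in the simulated groups (-0.52 to -0.48). With the Id1KO arrays split into 2 and 2, so that the comparisons shared none, the covariance over the 6 splits was between -0.33 and -0.31. The correlation was between -0.40 and -0.37, and 8544 to 8849 genes had opposite signs. The splits remove shared array errors, but not a difference of the Id1KO cultures from both other groups, nor the difference in array brightness between groups. The opposite signs thus do not by themselves show a return toward WT. With the slide as a block 11323 genes had opposite and 2588 equal signs.

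**Figure D5:**
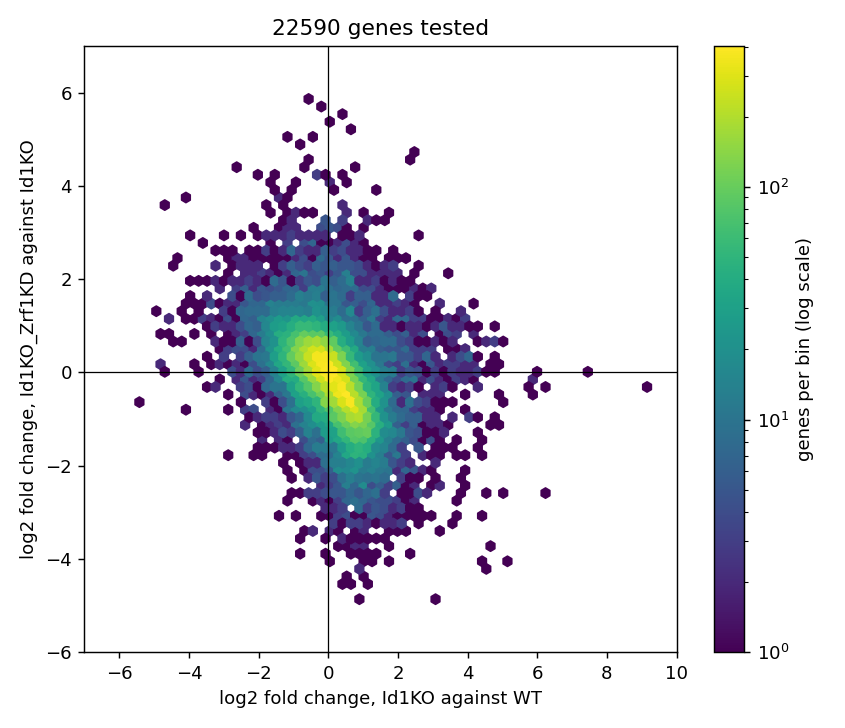
Log2 fold change in Id1KO_Zrf1KD against Id1KO (vertical) against that in Id1KO against WT (horizontal) for the 22590 genes tested, as counts per hexagonal bin on a log colour scale. More genes lie in the upper left and lower right quadrants, and 10538 of the 12881 genes that passed in both comparisons had opposite signs.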

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

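The tests of sex-linked genes, of dim probes and genomic DNA, and of fibroblast RNA were chosen after the results were seen, and those of slides and of other splits of the arrays were planned. The sex-linked genes separate WT from both groups of the Id1KO line, and 0 of 12 arrays had Y-linked genes out of place for their group. This argues against a single array exchanged between WT and the Id1KO line, or a WT array mixed with that line. The pattern of each group was read from the same arrays. The check cannot see an exchange between the 2 groups of the Id1KO line or a whole group mislabelled. Clustered germline gene families alone do not account for the X-linked difference, since 461 X-linked symbol genes outside them lay -0.23 from autosomal sets matched on level (SD 0.037), and a whole X chromosome more in WT is argued against, since in bins 7 to 10 these genes lay 0.26 above autosomal ones (193 genes, SD of matched sets 0.058), against -0.64 in bins 1 to 6 (268 genes). Different sex-chromosome content of the lines, including a loss or gain of part of the X, may account for part of it. The X-linked difference between the groups of the same line was -0.0444. Among symbol features it was -0.10 (unadjusted p = 0.0033 by the exact distribution of such medians), and -0.32 in Id1KO against WT. In bins 7 to 10 the symbol genes lay at 0.0962 in Id1KO_Zrf1KD against WT, and no test separated line content from an effect of the knockout on the X chromosome.

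Features without a gene symbol, among them Gm-number, Rik and receptor genes, lay higher in Id1KO, with a median of 0.44 against -0.04 for the others. The signal level of dim probes is argued against, since the median exceeded that of symbol sets matched on level by 0.43 (SD 0.0095). Genomic DNA that raised dim features of both kinds alike is argued against as the only cause. Dim symbol features lay at 0.0882 (bootstrap SD 0.022) and dim features without a symbol at 0.47. A smaller part due to DNA is not excluded, since true falls among symbol features could hide it. The difference in array brightness between the groups was not tested as a cause. A slide is argued against by differences of 0.42, 0.53 and 0.48 within the slides. A biological difference between the groups remains a hypothesis: transcripts of this mixed class may be more abundant in Id1KO, and the test values (0.43 and 0.42) do not say which.

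Fibroblast markers lay higher in Id1KO_Zrf1KD than in Id1KO. Fibroblast RNA in the cultures stays open: 22 of 22 markers rose, but stem cell genes would also have to fall, whereas the naive pluripotency list rose (shift 0.44; adjusted p = 0.054 with an estimated correlation) and the general one did not pass (shift 0.20, adjusted p = 0.54), and the fall that a small share would bring was not tested. Of the 22 markers, 20 were well above background on all WT arrays, so stem cells in these cultures express them or all cultures hold such cells. Of the endoderm list, 8 genes were taken, after its rise was seen, as ones that fibroblasts were assumed not to make. They were Gata4, Sox17, Foxa2, Sox7, Cubn, Amn, Hnf4a and Foxa1, and 8 of 8 rose (log2 fold changes from 0.85 to 2.68). As 19 of the 20 tested genes of the list rose, this outcome was nearly fixed when the 8 were taken, so it cannot decide the question. Only if the assumption holds would the rise of these 8 need a source other than fibroblast RNA. The assumption was not tested, and the matrix genes of the list, such as Col4a2, Lama1, Sparc and Lamb1, were not covered. A slide is argued against by a smallest shift of the markers within the slides of 2.16. A change of the stem cells themselves, from the knockdown or from the transduction, remains open and untested.

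With 8 arrays split into 4 and 4, 1 of 35 splits, the real one, called as many genes as the real one in each comparison. Every other split mixes the 2 groups, so few calls there follow from the separation of the groups. The splits show that the arrays separate by group. They cannot exclude a chance difference between lines, cultures or transductions. The real split called 15940 genes in Id1KO against WT, 16216 in Id1KO_Zrf1KD against Id1KO and 14547 in Id1KO_Zrf1KD against WT, and the highest of the other splits 1, 0 and 0.

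Among 382 groups of 4 values tested for the genes named and the array measures, 19 held a value set apart from the other 3, by a gap that is a large part of the group's range, where chance sets apart about 1 in 20. Id1KO_Zrf1KD replicate 3, the only array of its group on its slide (as is replicate 2), held 8 of them: the gap as a share of the range was 0.857 for Ccnd2, 0.870 for Col4a1, 0.861 for Id1, 0.830 for Kdr, 0.854 for Mirg, 0.885 for Sp5, 0.843 for Tead4 and 0.903 for Tgm2. In Id1KO_Zrf1KD it was 0.858 for Lamb1 and 0.852 for Pou5f1 in replicate 1, and 0.917 for Mmp10 in replicate 2. In Id1KO it was 0.919 for Hoxc13 in replicate 2 and 0.896 for Atf3 in replicate 4. In WT it was 0.848 for Fut1 and 0.895 for Zscan4a in replicate 1, 0.835 for Chac1 and 0.839 for Sparc in replicate 3, and 0.894 for Gbp2 in replicate 4. The 75th percentile of the processed signal of WT replicate 1, 440.7 units against 535.5 for the nearest other, was also set apart (0.866).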

How the results depend on the processing

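The settings with features with a gene symbol only, autosomal features only and arrays centred on the median of tested genes were chosen after the data were seen. Of 435 results of named genes 418 and of 84 list results 29 kept their direction and side of the threshold in every setting run, where a result that passed in neither setting counts as kept. Leaving out 1 array at a time gave 15578 to 16372, 15634 to 16337 and 13900 to 14622 genes in Id1KO against WT, Id1KO_Zrf1KD against Id1KO and Id1KO_Zrf1KD against WT. Signal over background limits folds of dim genes: with normexp, in that order, 1226, 767 and 1063 genes were higher and 914, 1331 and 768 lower by at least 2-fold, and with the deposited values 1064, 912 and 1018 were higher by that much, and 1154, 1146 and 819 lower. With features with a gene symbol only, which tests fewer genes, 10371 and 10129 genes passed in the first 2 comparisons, 4915 were higher (1160 by at least 2-fold) in the first, and 4079 and 4544 lower (784 and 941 by at least 2-fold) in the other 2. In this setting 6371 genes moved back, and X-linked genes differed from autosomal ones by -0.10 after the knockdown (unadjusted p = 0.0033 by the exact distribution of such medians).

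The Id1 fold change in Id1KO against WT passed with normexp (0.31), quantile normalization (0.37), the deposited values (0.36), the slide block (0.37) and the trended and robust variance (0.37), with adjusted p from 0.0016 to 0.048; without single arrays it was 0.25 to 0.49, and it passed without WT replicate 4, Id1KO replicate 3 or Id1KO_Zrf1KD replicate 3 (0.43, 0.49 and 0.37). The estimated correlation left 6 lists called in Id1KO against WT, no filter on dim probes gave 20 in Id1KO_Zrf1KD against Id1KO, and fry, which compares no list with other genes, gave 24, 26 and 26. Fry's direction was opposite to camera's for the Wnt list in Id1KO against WT (shift -0.17) and the imprinted list in Id1KO_Zrf1KD against Id1KO (shift 0.24). In Id1KO against WT, Kdr turned to -0.69 with the mean over its probes, since they differ in sign, and T, not well above background in Id1KO, to 0.00595 with normexp. Apart from Kdr and the settings with fewer genes, the cause was not tested.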

Other observations

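The test of another cause for the naive pluripotency shift was chosen after its result was seen, and the counts below were planned. Several lists that did not pass as a whole in Id1KO against WT or in Id1KO_Zrf1KD against Id1KO held genes that moved. Over all genes, 72.0% passed in the first and 72.1% in the second, so a list of any kind would hold such genes. The counts below describe the lists and were not tested against that share. Of 21 genes of the p53 and apoptosis list, 7 rose and 9 fell in Id1KO (adjusted p = 0.16), and Cdkn1a, the cell cycle inhibitor p21, was 3.28-fold lower on its brightest probe. After the knockdown 9 rose and 4 fell (adjusted p = 0.053, and 0.034 with the slide as a block), with Cdkn1a 3.33-fold and Phlda3 3.22-fold higher. The 3 probes of Cdkn1a had log2 fold changes of -1.71 to -0.41 in Id1KO and of -0.06 to 2.6 after the knockdown, so its size depends on the probe. The Polycomb list had 10 of 28 genes higher and 12 lower in Id1KO (adjusted p = 0.36), and 12 higher and 9 lower after the knockdown (adjusted p = 0.24).

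In the Wnt list 5 of 17 genes rose and 5 fell in Id1KO (adjusted p = 0.54), and 10 rose and 4 fell after the knockdown (adjusted p = 0.068), when Sp5 was 6.28-fold higher (3.57-fold at the lowest of the other scalings). The Notch list had 2 of 12 genes higher and 6 lower in Id1KO (adjusted p = 0.25), with its ligand Dll1 3.47-fold higher, and 1 higher and 5 lower after the knockdown (adjusted p = 0.45). In the germline list 11 of 19 genes rose and 6 fell in Id1KO (adjusted p = 0.37), as for Sycp3, a protein of the synaptonemal complex (3.31-fold higher), which was 2.75-fold lower after the knockdown, where 7 rose and 9 fell (adjusted p = 0.89). Of the 4 tested genes of the X-inactivation centre 2 rose and 1 fell in Id1KO (adjusted p = 0.82), and 1 rose and 3 fell after the knockdown (adjusted p = 0.32). These do not include Xist, which did not pass the detection filter, nor Tsix and Jpx, which were not found on the array.

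Whether other differences between the WT and Id1KO lines account for the lower naive pluripotency genes could not be decided. The shift of the list was -0.92 in Id1KO and -0.20 in Id1KO_Zrf1KD against WT, and the list also differed between the 2 groups of the Id1KO line (shift 0.44, adjusted p = 0.0012; adjusted p = 0.054 with an estimated correlation), which also differ in transduction and selection. This value leaves line differences and the knockout as explanations that cannot be told apart with what is read here as 1 line per genotype.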
